A study of Mus musculus with 8 samples.

How the data were processed

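Gene expression was measured in newborn mouse epidermis that had been separated from the dermis. The series holds 8 arrays, 4 from epidermis lacking both the insulin receptor and the IGF-1 receptor (the labels' IR-/-, IGF-1R-/-, called dKO) and 4 from wild-type controls. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised to Affymetrix Mouse 430 2.0 arrays, which measure each transcript with 1 or more probe sets near its 3 prime end. The labels call the samples biological replicates and do not say whether each came from a single animal. No batch or scan date was given in the sources used here.

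The deposited value table holds 1 intensity per probe set and array on a linear scale. MAS5 and Partek are named per the submitters' processing notes, with no role or version. Every array of the table had the same 2% trimmed mean of 250, as tested on the values, and no other normalization was found. The authors also deposited a table of their own comparison of knockout with control, with 2007 probe sets. Per the file headers it gives a ratio of knockout over control, a signed fold change made from that ratio, an F statistic used as a score for 1 factor called Strain, and an unadjusted p-value. Every entry of the authors' deposited table had an absolute fold of at least 1.5 and a p-value of at most 0.0499. The normalization behind its ratios is not given in the sources used here, and the ratios could not be recomputed from the value table.

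Gene names were taken from the authors' deposited table, because no annotation of the remaining probe sets was used here. Of its probe sets, 1804 had exactly 1 gene symbol, 71 had several, 130 had none and 2 had a symbol turned into a date. The 1804 probe sets stood for 1392 genes. Of these symbols, 1330 were found in the RefSeq gene table of the mouse, 147 of them under another current symbol, and 62 were not found. Symbols are printed as the authors' table gives them. A gene that is not named here was not shown to be unchanged. All named genes had been selected by the authors on these same arrays, so the direction of a gene list is not independent evidence.

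Of 45101 probe sets, 64 Affymetrix controls and 5 with a signal of 0 on an array were left out, and 45032 were tested. The deposited intensity values were converted to log2 without an offset and not normalized further. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with genotype as the single term. P values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and an adjusted p under 0.05 counted as changed. "Rose" and "fell" refer to that threshold. Levels are given as mean signal ± SD with n = 4 per group, and differences as log2 dKO minus control with a standard error. Per-gene signals have no detection call here, so a large difference of a dim gene depends on signals close to background. For many such genes the difference of log2(signal + 32) is given as well.

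Before the data were examined, 45 gene lists were fixed, and 14 of them had at least 5 named genes. Each of these was set against all named genes with limma's camera, at a preset correlation of 0.01, using for each gene the probe set with the highest mean. Camera p values were adjusted by the Benjamini-Hochberg method over the 14 lists, and camera with an estimated correlation and fry were run as alternatives. Member counts are given adjusted over all probe sets and adjusted over the list alone. The second count was largely set in advance, because the authors had selected the named genes by unadjusted p on these same arrays. It is no added support for a list. Among the 14 tested lists, the named share of the members ran from 5 of 36 FoxO target genes to 20 of 30 activation and stress genes. The plan had set each list against all genes on the array, and the missing annotation narrowed that background to the named genes.

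The genes to be named were also fixed beforehand. They were Insr and Igf1r, the 12 largest rises and 12 largest falls among named genes past the threshold at or above the median level with no overlap between groups, up to 4 members per list with the smallest p, and 20 preset genes. Of the preset genes, Foxo1, Krt15 and Irs2 had a name here. Genes named outside this rule are pointed out where they appear. For single values, an exact two-sided permutation test over all assignments of the 8 arrays was used, whose smallest possible p is 0.0286.

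The procedure was tested on simulated data made from the real means and spreads over 45032 probe sets. It recovered 63% of 100 probe sets changed by a log2 difference of 1 and 94% of 100 changed by 2. The changed probe sets were all drawn from those at or above the median level, so recovery of dimmer ones was not tested. Of 172 calls, 8.7% were not among the changed probe sets, and 0 calls were made when nothing was changed. A simulated list shifted by 1 on the log2 scale was recovered, and 0 of 13 unchanged lists were called. Each simulated probe set was drawn independently of the others. The lists called in the real data had estimated correlations of 0.073 to 0.85 between their genes. The simulation therefore does not show how often camera at the preset correlation calls unchanged lists of correlated genes. The precision is limited by the number of arrays, with a median standard error of 0.37 on the log2 scale.

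The alternatives were quantile normalization, centring each array on its median, 2 filters on dim probe sets, an offset of 32, the variance prior without the trend or with robust estimation, array weights, the replicate number as a block, and leaving out each array. Leaving out both arrays numbered 4, an ordinary F test on the value table, and the RNA quality ratio of each control gene alone were added after the data were seen. Figures were drawn with matplotlib 3.10.9. No coordinates are given, because no genome build was named in the sources used here.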

Results

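The series profiled newborn mouse epidermis from 4 dKO samples, which lack the insulin receptor and the IGF-1 receptor, and from 4 wild-type controls. Insulin and IGF-1 act through these receptors on growth, survival and metabolism in many tissues. The comparison asks which transcripts of the newborn epidermis differ when both receptors are missing. The median signal per array lay between 40.7 and 51.7 units, and array pairs correlated at 0.912 to 0.927 within the dKO group, 0.903 to 0.929 within controls and 0.897 to 0.918 between groups. Over the brighter probe sets, the first principal component held 42% of the variance. It placed the controls at -41.7 to -24.2, dKO replicates 1 to 3 at 30.7 to 63.8 and dKO replicate 4 at 4.5. RNA quality, as the log2 ratio of 3 prime to 5 prime control probe sets averaged over Gapdh and Actb, was 0.016 ± 0.040 in dKO and 0.11 ± 0.106 in controls (SD, n = 4 each; exact two-sided permutation p = 0.171). For Actb alone it was 0.485 ± 0.088 and 0.651 ± 0.108 (SD, n = 4 each; exact permutation p = 0.0571), and for Gapdh alone -0.453 ± 0.020 and -0.430 ± 0.129 (exact permutation p = 0.771).

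Both targeted receptor transcripts were lower in dKO. Insr, which encodes the insulin receptor, had a mean signal of 72.8 ± 16.1 in dKO and 254 ± 63.8 in controls (SD, n = 4 each). This was 3.47-fold lower, a log2 difference of -1.79 (SE 0.23, adjusted p = 0.00319, limma with Benjamini-Hochberg adjustment), and all 4 dKO arrays (50.7 to 87.6) lay below all 4 controls (176 to 309.6). Igf1r, the IGF-1 receptor, fell by 0.76 in its brightest probe set (SE 0.14, limma Benjamini-Hochberg adjusted p = 0.0176), from 582 ± 106 to 341 ± 27.7 units (SD, n = 4 each). Its second brightest probe set fell by 0.98 (SE 0.14, limma Benjamini-Hochberg adjusted p = 0.00438).

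The remaining pair of Igf1r probe sets disagreed in direction. The third brightest had a log2 difference of -0.65 (SE 0.16) and the dimmest one of 0.88 (SE 0.22), with limma Benjamini-Hochberg adjusted p of 0.0597 and 0.061. The position of these probe sets relative to the deleted parts of either gene is not given in the sources used here, so signal that remained in dKO says nothing about the deletion. In the authors' deposited table the ratios were 0.297 for Insr and 0.577, 0.549, 0.597 and 1.79 for the Igf1r probe sets from the brightest to the dimmest. The call of the brightest Igf1r probe set ended without dKO replicate 2, control replicate 1 or control replicate 2 (limma Benjamini-Hochberg adjusted p = 0.0593, 0.0753 and 0.0517).

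**Figure D1:**
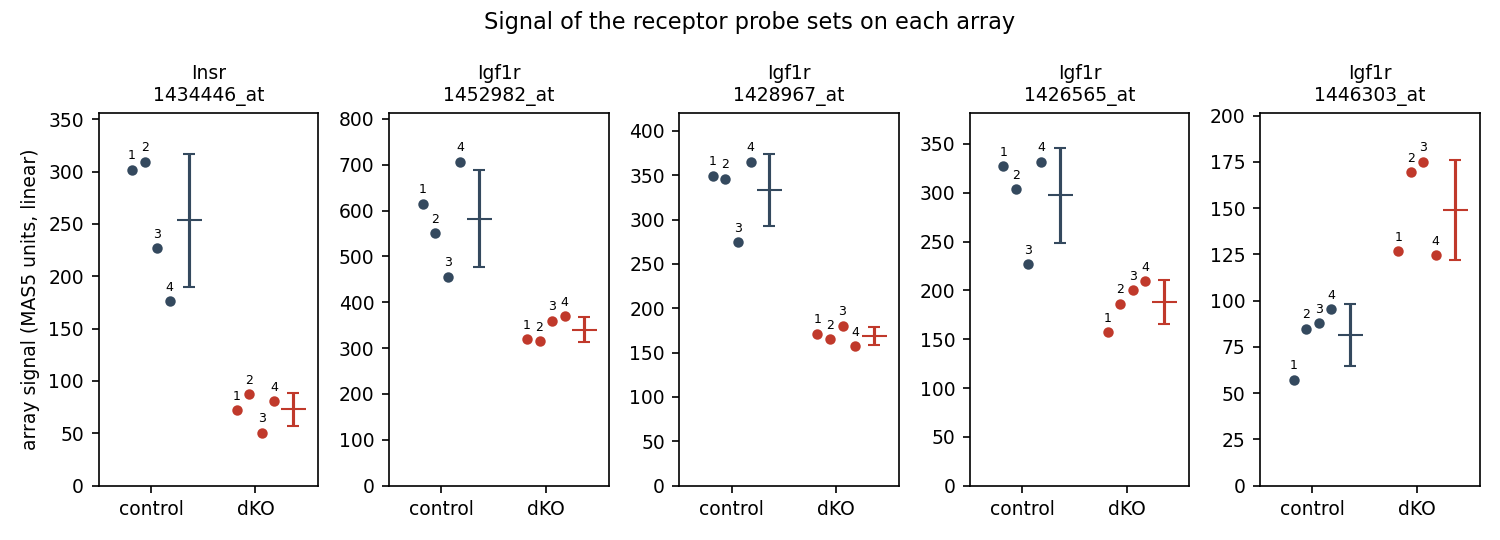
Signal of the Insr probe set and the 4 Igf1r probe sets on each array, on a linear axis that starts at 0. Points are arrays numbered by replicate, and bars give the mean ± SD of 4 arrays; Insr lay at 50.7 to 87.6 in dKO and 176 to 309.6 in controls, and the dimmest Igf1r probe set, on the right, was higher in dKO.

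The largest changes were ranked among named genes at or above the median level with no overlap between groups. Among the rises were the small proline-rich proteins Sprr2i (log2 difference 6.86, SE 0.97) and Sprr2f (6.55, SE 0.78), the chemokine Ccl20 (6.34, SE 0.47) and the glucose transporter Slc2a3 (5.48, SE 0.82). The protease inhibitor Slpi rose by 4.29, the cytokine Il33 rose 18.4-fold, and Chi3l1, a chitinase-like secreted protein, by 3.84. The first 4 were dim in controls, with mean signals of 9.20 to 16.7 units, and with 32 added to each signal the differences were 4.97 for Sprr2i, 4.41 for Sprr2f, 3.98 for Ccl20 and 3.07 for Slc2a3. Saa1, an acute phase protein, and Sprr2j (current symbol Sprr2j-ps) rose by 4.66 and 5.46. They were also dim in controls, with mean signals of 27.4 and 19.35 units, and with 32 added rose by 3.28 and 3.42. The largest falls of this ranking were Krt26, a keratin of the inner root sheath, and Cyp2g1, a cytochrome P450, at -4.36 (SE 0.92) and -4.34 (SE 0.44). Crym, Fa2h, Krtap8-1, Elovl3, Krt31, Mt4, Pcdh20, Igfbp5, S100a3 and Car6 followed, with log2 differences of -3.85 to -2.99. With 32 added, Krt26 stood at -2.78 and Crym at -2.49, and Cyp2g1 (-3.40) and Krtap8-1 (-2.82) ranked before Krt26. All 24 passed the threshold (limma, Benjamini-Hochberg), with adjusted p between 0.000224 and 0.0303.

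In all, 1012 of 45032 probe sets changed (limma, Benjamini-Hochberg), 447 higher and 565 lower in dKO, and 261 of the higher and 314 of the lower ones by at least 2-fold. Unadjusted p lay under 0.05 for 6763 probe sets, where chance gives 2252. In 983 of the 1012 the groups did not overlap, and over all probe sets this was so for 9.4%, where chance gives 2.86%. Among the 1392 named genes 270 rose and 309 fell, each by its brightest probe set, and 0 genes had probe sets that changed in opposite directions. The median difference of all probe sets was -0.068, and centring each array on its median moved it by 0.125 and turned the split to 607 higher and 322 lower. Quantile normalization moved it by 0.105, with 470 higher and 465 lower.

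The count depended on single arrays and on the variance model. It was 508 without dKO replicate 2, 438 without dKO replicate 3, 353 without control replicate 1, 431 without control replicate 2 and 529 without control replicate 3. Without the intensity trend it was 60, and of 82 named genes and receptor probe sets past the threshold 7 stayed past it, among them Ccl20, Cyp2g1 and Pcdh20. With every array left out in turn, 49 of the 82 stayed past it each time. Of the largest changes, Krt26, Krt31, Krtap8-1, S100a3, Crym, Saa1 and Sprr2j did not, with limma Benjamini-Hochberg adjusted p up to 0.114, 0.115, 0.103, 0.0903, 0.109, 0.0778 and 0.0651. Leaving out control replicate 1 or dKO replicate 2 ended the call of each of these 7 genes, and leaving out dKO replicate 3 that of each but Krt26. Control replicate 2 did so for Krt26, Saa1 and Sprr2j, control replicate 3 for Crym and Saa1, and control replicate 4 for Krt26, Crym and Krt31. Robust estimation of the variance ended the calls of these 7 and of Sprr2i, Il33, Slpi and Krt6b, with limma Benjamini-Hochberg adjusted p of 0.063, 0.0659, 0.102 and 0.0952 for the last 4. With 32 added, Krtap8-1 and Krt31 did not pass (limma Benjamini-Hochberg adjusted p = 0.0747 and 0.0692).

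**Figure D2:**
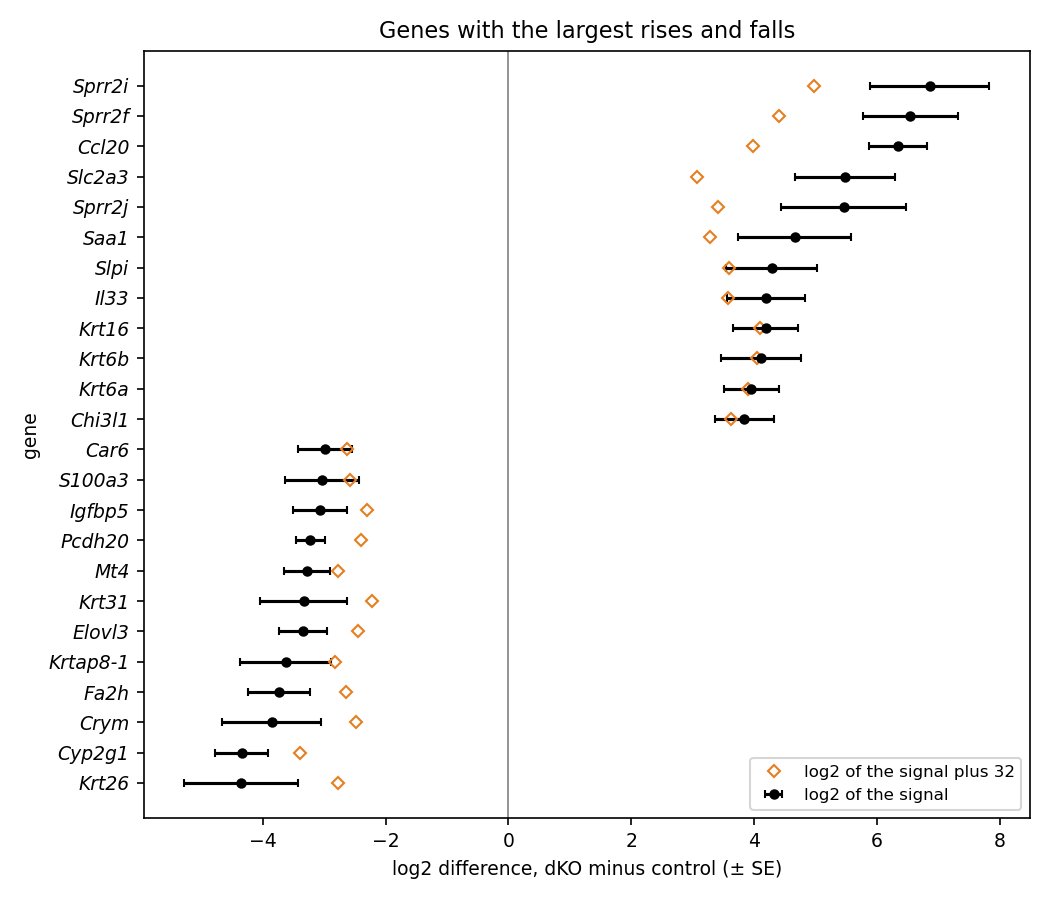
Log2 difference (dKO minus control) of the 12 largest rises and 12 largest falls among named genes at or above the median level with no overlap between groups, with bars giving ± SE from 4 arrays per group. Open diamonds give the difference after 32 was added to each signal, which shrinks the change of dim genes such as Slc2a3, from 5.48 to 3.07.

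Genes of activated or stressed keratinocytes rose together. For this and every list below, only members named by the authors' table were counted, which is not independent evidence of direction. Counts adjusted over the list alone were also largely set in advance by that selection and add no support. Of 20 named members of this list, 18 rose, 0 fell and 2 did not pass, and 20 were higher when adjusted over the list alone. The keratins Krt6a, Krt6b and Krt16, which epidermis makes after wounding and in inflammation, rose by 3.96 (SE 0.45), 4.11 (SE 0.66) and 4.19 (SE 0.53). Krt6a went from 1205 ± 1266 to 13480 ± 1290 units (SD, n = 4 each), a 15.5-fold difference. Ereg, a ligand of the EGF receptor, rose by 3.82 and the cytokine Il1f6 by 2.18 (limma Benjamini-Hochberg adjusted p = 0.000534 and 0.00027). Lcn2 (3.49) and Il1f9 (0.96), named after their values were seen, did not pass. The list mean was 3.35 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 5.98e-08; adjusted p = 0.33 with an estimated correlation).

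The activation genes also varied within groups. Krt6b read 6636 units in control replicate 4 and 376.8 to 714.8 in the other controls, and 14437 in dKO replicate 4 and 17187 to 19173 in the other dKO arrays. Averaged over the list and set against the control mean, dKO replicate 4 stood at 2.24 and dKO replicates 1 to 3 at 3.58 to 3.96, and control replicate 4 stood at 0.85 and the other controls at -0.36 to -0.19. With both arrays numbered 4 left out, 1525 probe sets changed, 714 higher and 811 lower.

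Cytokine and chemokine genes were higher in dKO. Of 11 named members 7 rose, 0 fell and 4 did not pass, and 11 were higher when adjusted over the list alone. Ccl20, which attracts lymphocytes and dendritic cells, went from 9.2 ± 6.94 to 652 ± 276 units (SD, n = 4 each). Besides Ccl20 and Il33, Cxcl16 rose by 1.03 (SE 0.17) and Cxcl14 by 0.67 (SE 0.11). Tnfaip3, Icam1, Nfkbia and Cxcl1, named after their values were seen, had differences of 0.71 to 1.19 that did not pass. The list mean was 2.09 (camera, Benjamini-Hochberg adjusted p = 0.000407; adjusted p = 0.33 with an estimated correlation).

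Among late differentiation genes, members of the Sprr2 and Lce3 families rose. Of 14 named granular and cornified envelope genes, 12 rose, 0 fell and 2 did not pass, and 12 were higher and 2 lower when adjusted over the list alone. Sprr1b, a precursor of the cornified envelope, rose by 3.65 (SE 0.41), Sprr2d by 3.42 (SE 0.37) and Sprr2h by 2.44 (SE 0.29). Casp14 and Tgm3, enzymes of terminal differentiation, had log2 differences of -0.67 and -1.03 that did not pass and were named after these were seen. Sprr1b, Sprr2d and Sprr2h also belong to the activation list. The list mean was 2.73 (camera, Benjamini-Hochberg adjusted p = 0.000407; adjusted p = 0.47 with an estimated correlation). Of 3 named spinous layer genes 3 rose, and Krt77, a suprabasal keratin, rose by 2.21 (SE 0.36), a call that robust estimation ended (limma Benjamini-Hochberg adjusted p = 0.0619). Leaving out dKO replicate 2 or 3 or control replicate 1 ended the calls of the other spinous genes, Tgm1 and Grhl3, and leaving out control replicate 2 or 3 that of Tgm1 (limma Benjamini-Hochberg adjusted p up to 0.0712 and 0.0849). Krt15, a keratin of basal cells, fell by 1.66 (SE 0.19, limma Benjamini-Hochberg adjusted p = 0.00136), from 11330 ± 2247 to 3591 ± 903 units (SD, n = 4 each). Itga3, the other named basal gene, differed by 0.45 and did not pass.

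Hair shaft and sebaceous gland genes were lower in dKO. Of 17 named genes of the hair shaft and inner root sheath, 12 fell, 1 rose and 4 did not pass, and 16 were lower and 1 higher when adjusted over the list alone. With 32 added to each signal 4 still fell, Krt33a, Krt34, Krt71 and S100a3. The hair keratins Krt33a and Krt34 had log2 differences of -5.57 (SE 0.96) and -4.93 (SE 0.91), or -3.03 and -2.60 with 32 added, and Krt71 of the inner root sheath fell by 2.86 (SE 0.55). Leaving out control replicate 1 ended the calls of Krt33a, Krt34 and Krt71, dKO replicate 3 also those of Krt34 and Krt71, and dKO replicate 2 that of Krt71, with limma Benjamini-Hochberg adjusted p up to 0.0558, 0.0728 and 0.0753. Robust estimation of the variance also ended these 3 calls. Krtap13, a hair keratin-associated protein named after its value was seen, rose by 4.57 (SE 0.91), from 7.05 ± 7.52 to 117 ± 108 units (SD, n = 4 each), and by 1.73 with 32 added. The list mean was -2.69 (camera, Benjamini-Hochberg adjusted p = 0.0069; adjusted p = 0.66 with an estimated correlation).

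Of 6 named sebocyte genes 6 fell, also when adjusted over the list alone. Scd1, a fatty acid desaturase, fell by 2.94 (SE 0.35) and Elovl3, a fatty acid elongase, by 3.35 (SE 0.39). Pparg, a regulator of lipid synthesis, fell by 4.02 (SE 0.58) from 47.9 ± 16.4 to 3.05 ± 1.17 units (SD, n = 4 each), and by 1.17 with 32 added. Soat1, which esterifies cholesterol, fell by 2.06 (SE 0.32). The list mean was -2.66 (camera, Benjamini-Hochberg adjusted p = 0.0069; adjusted p = 0.52 with an estimated correlation). Levels of these genes differed among controls, with Scd1 at 2344 and 2801 units in control replicates 1 and 4 and 927.6 and 930.9 in 2 and 3, and at 134.8 to 269.4 in dKO. Of 6 named genes of hair follicle morphogenesis, 1 rose (Krt17, 0.78) and 1 fell (Foxn1, -0.94), and 1 was higher and 5 lower when adjusted over the list alone. Its camera test with Benjamini-Hochberg adjustment gave an adjusted p of 0.538. Foxn1, a regulator of hair and keratinocyte differentiation, stayed past the threshold in 2 leave-one-out fits, without dKO replicates 1 and 4, with limma Benjamini-Hochberg adjusted p up to 0.102. Its call also ended with quantile normalization, median centring and the replicate number as a block.

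**Figure D3:**
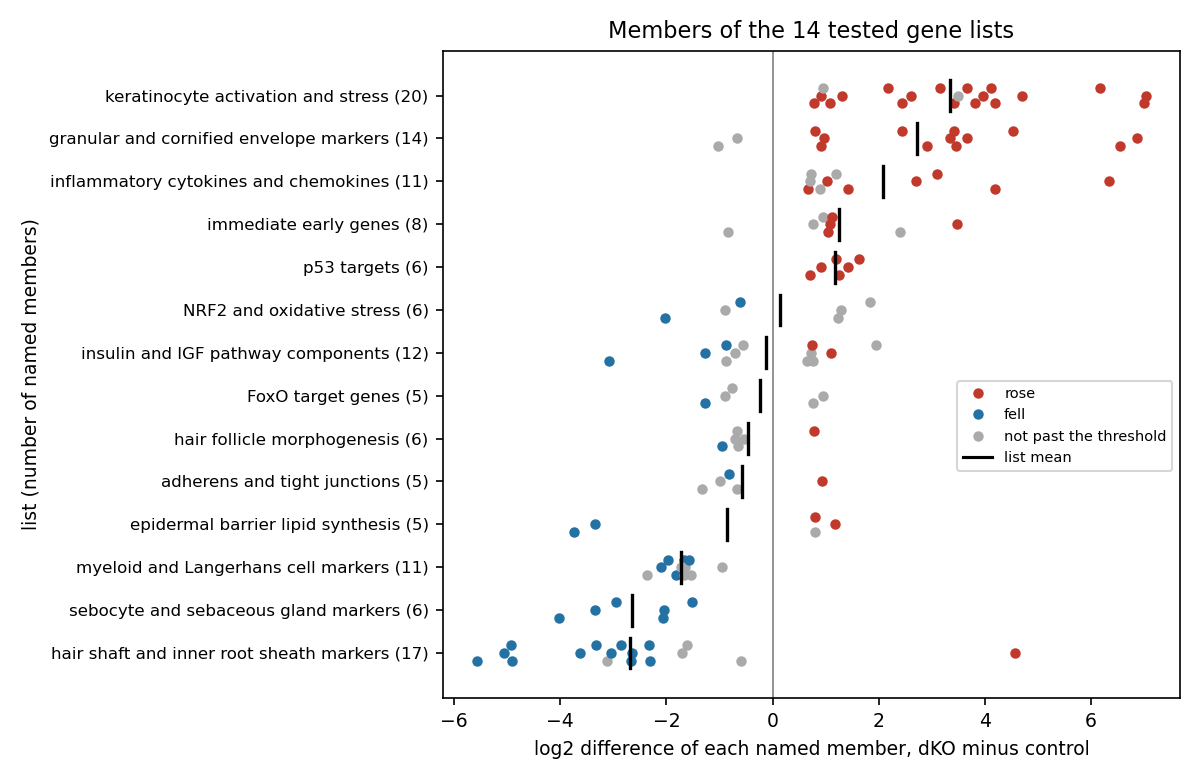
Log2 difference (dKO minus control) of each named member of the 14 tested gene lists, with the number of named members in brackets. Red points rose, blue points fell, grey points did not pass the threshold, and black bars mark list means, from 3.35 for activation genes to -2.69 for hair shaft genes.

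Markers of immune cells were lower in dKO. Of 11 named myeloid and Langerhans cell genes, 5 fell and 6 did not pass, and 11 were lower when adjusted over the list alone. With 32 added 3 fell. Ptprc, which encodes the leukocyte antigen CD45, fell by 2.10 (SE 0.27), and Csf1r, the receptor for colony stimulating factor 1, fell by 1.97 (SE 0.33), from 1038 ± 202 to 297 ± 167 units (SD, n = 4 each). The others that fell were Tyrobp (-1.57), C1qc (-1.67) and Fcer1g (-1.81), the last named after its value was seen. Leaving out control replicate 1 or 3 ended the call of Tyrobp, and leaving out any array but dKO replicate 4 ended that of C1qc, with limma Benjamini-Hochberg adjusted p up to 0.0592 and 0.138. The list mean was -1.73 (camera, Benjamini-Hochberg adjusted p = 0.00997; adjusted p = 0.66 with an estimated correlation). Of 4 named lymphocyte genes 3 fell, and 4 were lower when adjusted over the list alone or with 32 added. The call of Coro1a (-1.33) ended without dKO replicate 2 or 3 or control replicate 1, 2 or 3 (limma Benjamini-Hochberg adjusted p up to 0.0899). The T cell genes Cd3d and Cd3g fell by 3.93 (SE 0.51) and 2.11 (SE 0.35), and by 1.32 and 1.29 with 32 added. Both list means were lowest in dKO replicate 1. Set against the control mean, the myeloid list stood at -3.02 there and at -1.96 to -0.81 in the other dKO arrays. For the lymphocyte list these values were -3.49 and -2.27 to -1.885. On both lists every dKO array lay below every control.

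Markers of other cell types were mixed. Alas2, of heme synthesis in red cells, rose by 3.03 (SE 0.44), or 2.02 with 32 added. Tpm2, a tropomyosin, rose by 1.92 (SE 0.21) and Sparc, a matrix protein, by 0.74 (SE 0.15). Slc4a1 (1.325) of the erythroid list and Col5a1 (0.795), Fbn1 (1.05) and Fap (-1.39) of the fibroblast list did not pass. The calls of Alas2 and Tpm2 held without any single array, and that of Sparc ended without dKO replicate 2, dKO replicate 3 or control replicate 1 (limma Benjamini-Hochberg adjusted p up to 0.0725). Wif1, a Wnt inhibitor of the dermal papilla list, rose by 1.42 (SE 0.32), a call that held without dKO replicate 1 alone and ended with 32 added (limma Benjamini-Hochberg adjusted p = 0.0602). Of adipocyte markers Pparg fell and Retn (-1.35) did not pass. The 4 named Merkel cell genes, Isl1, Sox2, Atoh1 and Krt8, had differences of -2.52 to -0.96, or -0.89 to -0.61 with 32 added, and 0 passed. These 4 were lower when adjusted over the list alone, a count that the selection of named genes had largely set in advance. Tyrp1 of melanocytes (0.98) and Mbp of Schwann cells (1.10) did not pass. No named gene came from the endothelial or mast cell lists.

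**Figure D4:**
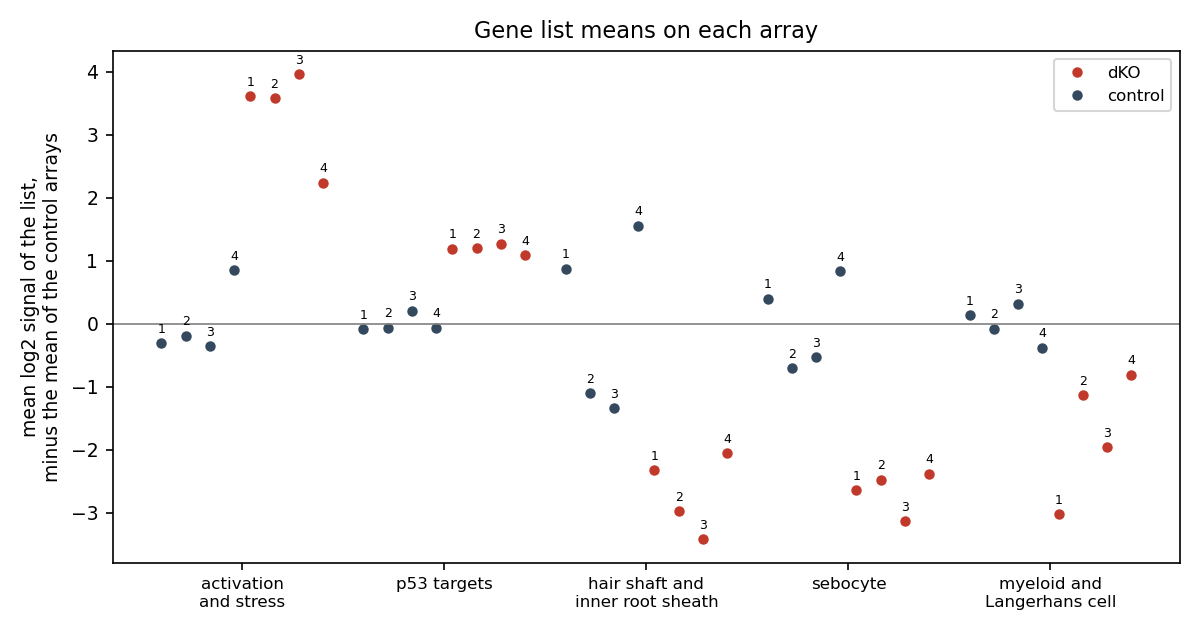
Mean log2 signal of 5 gene lists on each array, minus the mean of the 4 control arrays, with arrays numbered by replicate. Activation genes stood at 2.24 in dKO replicate 4 and 3.58 to 3.96 in the other dKO arrays, and hair shaft genes ranged from -1.33 to 1.56 among controls.

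The named target genes of p53 rose in dKO, and they were 6 of the 23 genes of the list. All 6 rose, also when adjusted over the list alone, with a list mean of 1.19 (camera, Benjamini-Hochberg adjusted p = 0.00229; adjusted p = 0.33 with an estimated correlation). The remaining genes of the list, the preset gene Cdkn1a among them, had no name here, so a rise of the whole list was not shown. Ccng1 rose by 1.20 (SE 0.12), Plk2 by 1.42 (SE 0.18), Pmaip1, a promoter of apoptosis, by 1.26 (SE 0.17), and Mdm2, the ubiquitin ligase that limits p53, by 0.92 (SE 0.13). The 4 calls held without any single array. Of 8 named immediate early genes 4 rose and 4 did not pass, and 7 were higher and 1 lower when adjusted over the list alone. Junb and Ier3, which also rose, lost their calls without dKO replicate 2 or 3 or control replicate 1 or 2, Junb also without control replicate 4 and Ier3 without control replicate 3 (limma Benjamini-Hochberg adjusted p up to 0.0853 and 0.117). Fosl1 and Maff rose by 3.48 (SE 0.48) and 1.08 (SE 0.14), and the list mean was 1.25 (camera, Benjamini-Hochberg adjusted p = 0.0139; adjusted p = 0.52 with an estimated correlation). In the brightest 25% of probe sets the call of this list was lost (camera, Benjamini-Hochberg adjusted p = 0.188).

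Components of insulin and IGF signalling moved both ways. Of 12 named members 2 rose, 3 fell and 7 did not pass, and 5 were higher and 6 lower when adjusted over the list alone. The binding proteins Igfbp2 and Igfbp5 moved apart, with differences of 1.09 (SE 0.14) and -3.07 (SE 0.43). Igfbp7 rose by 0.75 (SE 0.17), a call that held in the fit without control replicate 4 and ended in the other 7 leave-one-out fits and with 32 added (limma Benjamini-Hochberg adjusted p up to 0.132). Pik3r3, a regulatory subunit of PI3 kinase, fell by 1.27 (SE 0.19). Foxo1, a transcription factor that insulin signalling keeps out of the nucleus, fell by 0.88 (SE 0.20, limma Benjamini-Hochberg adjusted p = 0.0455). Its call held in 1 of the 8 leave-one-out fits, that without dKO replicate 4, and ended with quantile normalization, median centring and 32 added. Irs2 differed by 0.77 (SE 0.20) and did not pass (limma Benjamini-Hochberg adjusted p = 0.0756). The list's mean (-0.12) and median (0.048) differed in sign, and camera gave a Benjamini-Hochberg adjusted p of 0.904. Of 5 named FoxO target genes 1 fell, Sesn3 with a difference of -1.28 (SE 0.20), and 2 were higher and 3 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.904). The other 4 did not pass, and the rest of the 36 genes of the list had no name here.

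Barrier lipid genes also moved both ways. Of 5 named members Sptlc3 and Ugcg, enzymes of ceramide and glucosylceramide synthesis, rose by 0.80 (SE 0.14) and 1.18 (SE 0.21). Elovl3 and Fa2h fell, with differences of -3.35 and -3.73, and Degs1 (0.81), named after its value was seen, did not pass. Elovl3 also belongs to the sebocyte list, so its fall is not a separate result here. Adjusted over the list alone, 3 were higher and 2 lower. The mean was -0.86 and the median 0.80, and camera, which sets the test statistics of a list against those of the other named genes, pointed up (Benjamini-Hochberg adjusted p = 0.891). The call of Ugcg ended without dKO replicate 3 or control replicate 1, 2 or 3 (limma Benjamini-Hochberg adjusted p up to 0.0589).

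The fit and the authors' deposited table, made by different processing of the same arrays, were set side by side. Of its 2007 probe sets, 873 were higher and 1134 lower in the knockout. Of the 2006 in the fit, 2004 (99.9%) had the same direction, and 818 passed the threshold, 379 higher and 439 lower. Another 194 probe sets that changed in the fit were outside the table. Across probe sets, which are not independent replicates, the log2 ratios of the table correlated with the fitted differences at 0.942. The median size was 0.83 in the authors' deposited table and 0.934 in the fit. For several dim genes the authors' deposited table gave smaller changes. Its ratios were 14.7 for Ccl20, 11.5 for Slc2a3, 0.511 for Pparg and 0.454 for Cd3d. In the same order, the fit gave ratios of 80.8, 44.7, 0.0617 and 0.0655. The brighter Krt6a was not smaller there, with 18.5 in the authors' deposited table and 15.5 in the fit. An ordinary F test on the value table, at an unadjusted p under 0.05 and at least 1.5-fold, gave 3498 probe sets. Of these 1568 were in the authors' deposited table, and the rest met the same cutoffs but had no name here.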

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

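A Dixon test for 1 array apart from the other 3 of its group was run on each named gene and on the mean of each tested list, and 17 of 266 groups passed its 5% level. Chance alone passes about 1 in 20. The 2 tests of RNA mixing, the test of dilution and the list differences with 32 added below were chosen after the results were seen.

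In dKO, replicate 4 was lowest for Cyp51 (0.892), Fa2h (0.907), Il1f6 (0.838) and Sprr2d (0.837) and highest for Gata3 (0.876). Replicate 1 of dKO was lowest for Gsta2 (0.839), Gstm2 (0.846), Irs2 (0.856), Krt77 (0.915), Prom1 (0.911) and Wif1 (0.909). Among controls, Bst2 was lowest in replicate 2 (0.917), Irs2 in replicate 3 (0.914), and Ccng1 (0.858) and Pcdh20 (0.862) in replicate 4. The activation list mean was highest in control replicate 4 (0.857), and the p53 list mean was highest in control replicate 3 (0.913).

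The arrays numbered 4 stood between the groups in their activation genes. If control RNA had entered dKO replicate 4, every gene would move toward the control level by the same share, but its Insr signal kept 0.94 of the dKO difference while S100a9, chosen after its values were seen, kept 0.015 and the activation genes a median of 0.474. Its 3 prime to 5 prime ratio of 0.05 lay inside the range of the other arrays, -0.039 to 0.248, which does not point to poorer RNA. In control replicate 4 the median dKO-like share of the activation genes was 0.129, but 0.36 for Krt6b, 0.50 for Insr and -0.83 for Igf1r, and Slc2a3 read 2.2 units against at least 313.5 in every dKO array, which 1 share of mixed RNA does not give. A lesser state of activation in dKO replicate 4, or some activation in control replicate 4, could give such uneven shares, and no test here tells these apart from other causes.

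Myeloid markers were lower in dKO. Array scaling does not account for this, because the weaker of 2 other scalings left a list mean of -1.60. Dilution by keratinocytes would lower all other cell types alike. The mean of 12 markers of dermal and blood cells (4 rose, 1 fell) was nonetheless higher. It stood 2.09 (SE 0.18) above that of 8 markers of Merkel cells, melanocytes and lymphocytes (0 rose, 3 fell), and 1.36 (SE 0.11) with 32 added. These standard errors do not cover the spread among markers. The 12 differences ran from -4.02 (Pparg, also a sebocyte gene) to 3.03 (Alas2). Only markers named by the authors' deposited table entered either mean. Dermal and blood signals also depend on how much of these tissues stayed with the separated epidermis. The comparison therefore cannot exclude dilution of cells that live in the epidermis. Fewer of several cell types that live in the epidermis remain possible, as lymphocyte markers were also lower. The named Merkel cell genes had lower means as well, but 0 passed. Lymphocyte and myeloid means differed by -0.71 (SE 0.24) and with 32 added by -0.10 (SE 0.17), so dim signals carry most of the gap, and this does not decide between a general loss of leukocytes and separate losses.

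Hair shaft, inner root sheath and sebocyte genes were lower in dKO. Scaling left means of -2.53 or stronger. Set against the control mean, the shaft list stood at 0.88 and 1.56 in control replicates 1 and 4. In control replicates 2 and 3 it stood at -1.10 and -1.33. For the sebocyte list these values were 0.40 and 0.84, and -0.71 and -0.53. The dKO arrays were lower, at -3.42 to -2.05 and -3.13 to -2.38. What caused the spread among controls was not tested. Follicles may have stayed in the dermis when the layers were separated. This would lower early follicle genes as much as shaft genes only if both were expressed in follicles alone, which was not tested. Morphogenesis genes without Krt17 were lower by less than shaft genes, with a difference of the means of 1.99 (SE 0.81). The margin set beforehand did not allow for dim shaft genes, since with 32 added the difference was 1.33 (SE 0.69), under 2 standard errors, so the separation, follicle number and follicle maturity stay open.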

How the results depend on the processing

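The main result was compared with each alternative, of which leaving out both arrays numbered 4 was added after the data were seen. The direction of all 8 called lists held throughout. Of the results for named genes 1719 kept the same call, 281 were weaker, 62 stronger and 1 reversed.

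The number of changed probe sets (1012 in the fit above, 447 higher and 565 lower) ranged from 353 to 1417 when 1 array was left out, with 185 to 624 higher and 158 to 793 lower. Without the intensity trend it was 60 (20 higher, 40 lower), and Insr at -1.79 and Igf1r at -0.76 no longer passed (limma Benjamini-Hochberg adjusted p = 0.0662 and 0.158). Array weights gave 1599 (709 higher, 890 lower), and leaving out both arrays numbered 4 gave 1525 (714 higher). Robust estimation of the variance gave 958 and ended the calls of 17 named genes. Median centring left 322 lower, and the brightest 25% of probe sets left 350 lower. With the replicate number as a block 698 changed. Same-number pairs correlated at 0.043, 0.025, -0.028 and -0.088, and pairs of unlike number at -0.145 to 0.165. No shared effect of the number was seen, but this cannot exclude that the samples were paired.

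With 32 added, 5 cytokine genes, 10 granular and cornified envelope genes, 5 sebocyte genes and 5 hair shaft genes (4 lower, 1 higher) passed the threshold, where 7, 12, 6 and 13 (12 lower, 1 higher) had passed.

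With an estimated correlation 0 lists passed, and 5 passed among the brightest 25% of probe sets. Overlap of direction with the authors' deposited table was 100% under both level filters.

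For the receptors, Igf1r ranged from -0.87 to -0.66 when 1 array was left out, and its probe sets below the threshold read -0.65 and 0.88. Bst2, which did not pass, ranged from -0.11 to 0.51 and had the reversed sign without control replicate 2.

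Reversed list directions were all in lists that did not pass. The list NRF2 and oxidative stress read -0.20 at or above the median level, 0.017 to 0.29 when 1 array was left out (camera pointed down at 0.14 without dKO replicate 1), and 0.14 with fry. The list insulin and IGF pathway components read -0.058 in the brightest 25% and -0.12 with fry, and the list epidermal barrier lipid synthesis -0.86 with fry, where camera had pointed up. The list FoxO target genes ranged from -0.33 to -0.086 when 1 array was left out.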

Other observations

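Several smaller lists had fewer than 5 named genes and were not tested as sets. Both named genes of the list of ribosome biogenesis and MYC targets rose, Myc, a growth regulator, by 1.08 (SE 0.14) and Tfrc, the transferrin receptor, by 0.76 (SE 0.18). The call of Tfrc held in 1 leave-one-out fit, that without control replicate 4. In amino acid and ATF4 stress response, Stc2, Slc7a11 and Asns had differences of 1.10, 1.23 and 0.76, and 0 of 3 passed. Of 4 clock genes Tef fell by 0.69 (SE 0.15), and Npas2, Per3 and Dbp had differences of -1.33 to -0.65, or -0.63 to -0.48 with 32 added, that did not pass. The call of Tef held only in the fits without dKO replicate 1 and dKO replicate 4.

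Among p63 target genes Grhl3, a regulator of barrier formation, rose by 0.76 (SE 0.15), and Fras1 (-1.02), Itga3 (0.45) and Satb1 (-2.40, or -0.83 with 32 added) did not pass. The call of Grhl3 ended without dKO replicate 2, dKO replicate 3 or control replicate 1, with limma Benjamini-Hochberg adjusted p up to 0.0849. Of the glycolysis list the transporter gene Slc2a3 rose, and Pfkp (0.55) and Slc16a3 (1.06) did not pass. In cholesterol synthesis Cyp51 rose by 0.59 and Sc5d fell by 0.89, and each call ended in 6 of 8 leave-one-out fits, holding for Cyp51 without either array numbered 4 and for Sc5d without dKO replicate 1 or 4. The interferon gene Rsad2 rose by 1.63 (SE 0.33), a call that ended without dKO replicate 1 or 2 or control replicate 1, 2 or 3, and Bst2 (0.28) did not pass. In tight junctions Cldn4 rose by 0.93 (SE 0.21), Marveld2 fell by 0.83 (SE 0.19) and 3 did not pass, and both calls ended in 7 such fits, holding for Cldn4 without control replicate 4 and for Marveld2 without dKO replicate 4. In the list NRF2 and oxidative stress Gsta2 fell by 2.02 (SE 0.38), Gstm2 by 0.61 (SE 0.13), and 4 did not pass. Adjusted over the list alone, 3 were higher and 3 lower, and of the 5 junction genes 1 was higher and 4 lower. Leaving out control replicate 1, 2 or 3 ended both calls, with limma Benjamini-Hochberg adjusted p up to 0.0715 and 0.121, and leaving out dKO replicate 2 or 3 also ended that of Gstm2. Camera on this list gave a Benjamini-Hochberg adjusted p of 0.904, and on the junction list one of 0.538. Rps6 (0.44), Hes1 (-0.62) and Pard6b (0.76), each the single named gene of its list, did not pass.

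The splits and neighbouring genes below were chosen as tests before the results were seen. Of the 35 splits of the 8 arrays into equal groups, 1 gave as many changed probe sets as the real one, the real one itself, with 1012 against at most 6 in the others. For the 8 called lists, 4 of 35 splits gave as many, and the highest other split also gave 8. The other splits with 8 lists each kept all but 1 of the dKO arrays together, so they held part of the real contrast. Splits with as many dKO as control arrays on each side gave at most 5 lists. The count over splits therefore cannot decide whether a chance division gives 8 lists. The set tests add little to the gene results, as the named genes were selected on these arrays.

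A possible cause to be tested was DNA of another strain carried along around the targeted genes, which could change neighbouring transcripts. Among the 100 genes nearest to each, 3 were in the authors' table for Insr and 8 for Igf1r, where windows across the genome had a median of 6 and a 95th percentile of 12. At most 70.3% of 21631 windows had a lower share. This does not point to a cluster of changed genes there, and it cannot exclude an effect on a few neighbours.

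Some of these results lead to further measurements. Whether the rise of Ccng1, Mdm2 and Pmaip1 comes with more p53 protein or with cell death could be tested by staining and by counting dying cells. Whether the loss of Krt15 (-1.66) reflects fewer basal cells could be tested by counting cells per layer. Detection of myeloid and lymphocyte antigens by staining of the same sheets would test whether cell number or expression per cell differs, which the array means (-1.73 and -2.43) cannot separate.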
